A study of Mus musculus with 26 samples.

How the data were processed

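FLAG ChIP-seq was done in MEFs from E13.5 embryos heterozygous for an EGFP knock-in at the tau locus, at passage 3, after 48 h in 2 µg/ml doxycycline. Chromatin of 60 to 100 × 1e6 cells was sheared to fragments of 200 to 500 bp and precipitated with FLAG M2 beads, with 1% kept as input. There were 13 IPs and 13 inputs in 5 groups: Ascl1 (3 IPs), Myod1 (4), Myod1+Myt1l (2), the swap construct (2) and the rtTA control (2). Bowtie2 2.1.0, MACS2 2.1.1 and DiffBind 1.16.3 and the genome build mm10 are named per the submitters' processing notes. The analysed files were 5 deposited peak lists, 1 per group, each entry with a position and a score. The score is the value deposited by the authors, and its scale is not given in the sources used here. The wording of the deposited lists speaks of merged, reproducibility-filtered peaks, and no further role of a tool was assumed. Signal tracks were not used here, and per-IP values were not analysed here. Read depth is not given by these lists, so precision rests on counts of peaks, and 95% Wilson intervals cover counting error only.

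The Ascl1 list fell into 3 and the Myod1 list into 6 blocks of entries in order of score, as many as there are pairs of IPs, and the other lists into 1. That a block stands for a pair of IPs is an inference from the file. Overlapping entries of a list were merged into peaks with the highest score and the number of blocks kept. Peaks that overlapped a control peak by at least 1 bp were removed from the 4 factor lists. Positions count from 1.

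Peaks were shared when they overlapped by at least 1 bp. Each share was set against 1000 shifts of the peaks along their own chromosomes, whose smallest p is 0.001 one-sided and 0.002 two-sided. Score ranks of shared and unshared peaks were compared by 100000 resamples, whose smallest p is 1e-05. Ascl1-only, shared and Myod1-only sites were formed from the Ascl1 and Myod1 lists, and the occupancy of these classes by the other constructs was compared by Fisher's exact test, two-sided, with sample odds ratios and exact conditional 95% intervals. Location was the peak midpoint within 1 kb of a gene end, inside a gene span, or elsewhere. The gene table gives neither strand nor exons, so the planned classes by transcription start site, exon and intron gave way to gene ends and gene spans.

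A gene had a peak when a peak midpoint lay within 5 kb of either gene end. Of the protein-coding genes, 21788 were used, after genes listed within the first 3 Mb of an autosome or X, where this build holds no sequence, or on no known chromosome were set aside. The 10 gene lists, written by hand from general knowledge, held 434 genes: proneural and Notch (42), neuronal structural and synaptic (70), myogenic regulators (43), muscle contractile (73), fibroblast (52), E proteins and Id proteins (7), cell cycle (35), housekeeping (32), liver (40) and haematopoietic (40). Each list was tested against all other genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 20 tests of Ascl1 and Myod1, the 20 of the swap construct and Myod1+Myt1l, and the 10 of the control. The difference between a pair of peak lists compared members with a peak of 1 list alone with the same split over all other genes, adjusted over the 10 gene lists. The threshold was 0.05.

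Genes were named by a rule. For each pair of peak lists and each gene list, members were sorted into those with a peak of the first list alone, of both, of the second alone or of neither, and up to 3 per class could be named, ordered by number of peaks and then by the alphabet. The genes of the introduced factors and Mapt, the 10 genes with most peaks and the 3 highest-scoring peaks of each list were added. The methods were tested on simulated data. A planted share of 30% was recovered as 30.0% and a planted odds ratio of 4 as 4.00. Of 200 random lists of 42 genes 5 passed 0.05, and of 200 lists planted at odds of 3, 176 passed. The 12772 merged Ascl1 peaks and the 7166 that overlapped Myod1 were the same with bedtools.

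Alternatives were an overlap of 50% of the shorter peak, midpoints within 100 bp, peaks set to 200 bp, control peaks kept, the higher-scoring 50% of peaks, the Myod1 list reduced to the length of the Ascl1 list by score or at random (100 draws), autosomes alone, random draws from the other lists, gene windows of 1 and 50 kb, a location window of 2.5 kb, the nearest gene within 100 kb, and a background of genes with a factor peak within 50 kb. Others were chosen after the data were seen: peaks found in every block, single blocks, the strongest Ascl1 and Myod1 peaks in the number of the swap list, the gene span extended by 5 kb, and the transgene loci left out. The score-based reduction of Myod1 for the gene lists and the per-list difference between the swap construct and Myod1+Myt1l were also chosen then. E-box motifs were not analysed here, since genome sequence was not used here. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and bedtools 2.31.1.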

Results

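Chromatin occupied by FLAG-tagged transcription factors was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse embryonic fibroblasts (MEFs), connective tissue cells isolated from E13.5 embryos, after 48 h of doxycycline. Ascl1 is a basic helix-loop-helix (bHLH) factor of neuronal differentiation, Myod1 is a bHLH factor of skeletal muscle differentiation, and Myt1l is a zinc finger repressor expressed in neurons. The question stated for the series was how far Myod1 also binds in the way a pro-neuronal factor does. The 26 samples held 13 FLAG immunoprecipitations (IPs) and 13 inputs. There were 3 IPs of Ascl1, 4 of Myod1, 2 of Myod1 with Myt1l, 2 of a Myod1 that carried the basic and C-terminal parts of Ascl1 (the swap construct), and 2 of a control that received the reverse tetracycline transactivator (rtTA) and no FLAG-tagged factor.

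The analysed values were 1 peak list per group. Values per IP were not analysed here, so no difference between lists could be set against a spread between replicates, and the exact tests compare these lists, not replicated conditions. The labels do not say whether the IPs of a group came from separate cultures or animals. The Ascl1 list held 22495 entries in 3 score-ordered blocks and merged into 12772 peaks with a median width of 364 bp. The Myod1 list held 59435 entries in 6 blocks and merged into 20944 peaks with a median width of 452 bp. Of the Ascl1 peaks, 56.9% stood in 1 block alone and 32.7% in all 3. Of the Myod1 peaks, 37.7% stood in 1 block alone and 18.4% in all 6. The Myod1+Myt1l, swap and control lists had 1 block each, with 3551, 3419 and 1125 peaks. Read depth is unknown from these lists, and a longer list shares more peaks for that reason alone, so shares are given in both directions. The 95% Wilson intervals cover counting error only. Each peak's score is the authors' own, on a scale not given in the sources used here, and was compared only within a list.

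The rtTA control measured what the FLAG beads recovered from cells that lacked a FLAG-tagged factor. Control peaks lay at neuronal genes: 27 of the 70 genes of the neuronal structural and synaptic list (38.6%, interval 28.0 to 50.3) had a control peak within 5 kb of a gene end, against 3.25% of all other protein-coding genes. Chga, which encodes a protein of secretory granules, Snap25, which encodes a vesicle fusion protein, and Syp, which encodes a synaptic vesicle protein, were among them; these examples were chosen after their values were seen. The odds ratio was 18.7 (interval 11.0 to 31.2; Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 4.7e-21 over 10 gene lists), and the other 9 lists did not pass. The strongest control peaks lay on chromosome 7 at 6410047 to 6410393 near Smim17 (score 138), on chromosome 9 at 21950297 to 21950665 near Plppr2 (score 124), and on chromosome 15 at 84829430 to 84829746 inside Phf21b (score 101), all in build mm10. Each of these 3 also lay in the Myod1, Myod1+Myt1l and swap lists and in none of the Ascl1 peaks. The 3 highest-scoring swap peaks, near Plppr2 (score 56.8), inside Xkr6 (48.0) and inside Garnl3 (46.3), all overlapped a control peak. So did ranks 2 and 3 of the Myod1+Myt1l list, inside Phf21b and near Plppr2, but not its rank 1. None of the 3 highest-scoring Ascl1 or Myod1 peaks overlapped a control peak.

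Few Ascl1 peaks overlapped a control peak, 89 of 12772 (0.697%, interval 0.567 to 0.857). The share was 2.20% for Myod1 (460 peaks, 2.01 to 2.40), 4.90% for Myod1+Myt1l (174 peaks, 4.24 to 5.66) and 8.72% for the swap construct (298 peaks, 7.82 to 9.71). Peaks shifted along their chromosomes overlapped the control at 0.0340 to 0.131% on average, and each list exceeded all 1000 shifts (permutation test, one-sided, p = 0.001, the smallest these shifts can give). In the other direction, 42.04% of the 1125 control peaks met a Myod1 peak and 26.7% a swap peak. For Myod1+Myt1l it was 15.8% and for Ascl1 8.44%. The order of the swap and Myod1 lists thus turned, and the Myod1 list was the longer of the pair. Peaks that overlapped a control peak were removed from all further comparisons, which left 12683, 20484, 3377 and 3121 peaks. The removal bore on neuronal genes: it lowered the members of the neuronal list with a nearby peak from 16 to 2 for the swap construct, from 14 to 7 for Myod1+Myt1l, from 26 to 16 for Myod1 and from 11 to 10 for Ascl1.

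The genes that encode the introduced factors are described before the removal of control peaks. Peaks inside the Ascl1 and Myod1 genes were found in the lists of constructs that carried a part of that factor. Myt1l also had peaks of constructs without it. Inside the Myod1 gene (chromosome 7, 46376474 to 46379092) the Myod1 list had 3 peaks, each found in all 6 blocks, and the highest-scoring one spanned 46376618 to 46377360 (score 58.9). The Myod1+Myt1l list had 3 peaks there, and the one at 46378099 to 46378432 was the strongest of its whole list (score 52.5). The swap list had 1 peak, at 46376658 to 46377195 (score 22.4), and the Ascl1 list had none. Inside the Ascl1 gene (chromosome 10, 87490819 to 87493660) the Ascl1 list had a peak at 87492369 to 87493143 (score 52.1), found in 1 of 3 blocks. The swap list also had a peak there, at 87492375 to 87492649 (score 11.5), and the Myod1 and Myod1+Myt1l lists had none. Over the Myt1l gene (chromosome 12, 29527590 to 29923216) the Myod1+Myt1l list had 3 peaks, of which the one at 29849204 to 29849509 ranked 8 in that list, while the Ascl1 list had 3, the Myod1 list 2 and the swap list 0. Mapt, the tau gene that carries the EGFP knock-in of these MEFs (chromosome 11, 104229409 to 104332090), held 3 Ascl1, 6 Myod1, 2 Myod1+Myt1l and 1 swap peak. The control list had no peak at any of these 4 genes. Reads from integrated cDNA cannot be told from reads of the endogenous gene in a peak list.

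**Figure D1:**
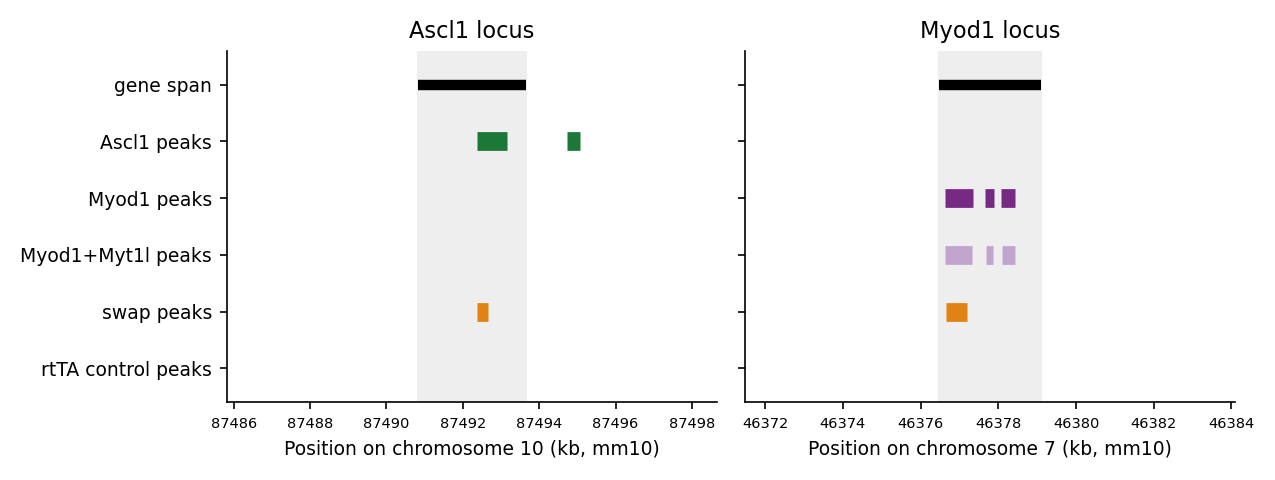
Peaks of each list along the Ascl1 gene (left) and the Myod1 gene (right), with the position in kb of build mm10 on the horizontal axis, 1 row per list, and the gene span in black and grey. The swap list has 1 peak inside each gene, the Ascl1 list has none at Myod1, and the Myod1 list has none at Ascl1.

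Ascl1 and Myod1 bind related E-box sequences and drive cells towards neuronal and muscle fates. The comparison of their lists asked how many sites in MEFs the neuronal and the muscle factor have in common. Of the Ascl1 peaks, 55.8% (7082 of 12683, interval 55.0 to 56.7) overlapped a Myod1 peak, and 34.2% of Myod1 peaks (7013 of 20484, 33.6 to 34.9) overlapped an Ascl1 peak. Shifted peaks gave 0.811% and 0.502% on average (permutation test, one-sided, p = 0.001, the smallest possible). All 4 factor lists also exceeded their shifts against the control, which had no FLAG-tagged factor. Passing this test, here and for the other constructs, thus does not by itself separate shared factor binding from regions recovered for other reasons. Shared sites had the higher scores in both lists: the median score percentile was 57.8 for shared against 41.5 for unshared Ascl1 peaks, and 69.2 against 41.6 for Myod1 peaks (permutation tests, two-sided, p = 1e-05 each, the smallest that 100000 resamples can give). A merged peak keeps the highest score of its blocks, whose score ranges differ, so its rank also reflects which blocks held it. The strongest Ascl1 peaks, inside the dynein gene Dnah2 (chromosome 11, 69459820 to 69460573, score 229), inside Plcl1 (chromosome 1, 55523865 to 55524361) and 17541 bp from Ifitm7 (chromosome 16, 14004247 to 14004569), were all in the Myod1 list. The strongest Myod1 peaks, inside the kinase gene Aak1 (chromosome 6, 86958558 to 86959420, score 115), inside Ripor3 (chromosome 2, 168023389 to 168024236) and 44306 bp from Gpc1 (chromosome 1, 92786982 to 92787695), were all in the Ascl1 list.

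Between single blocks, 2 Ascl1 blocks shared 39.5 to 89.4% of their peaks (median 80.9%) and 2 Myod1 blocks 30.1 to 86.9% (median 66.1%), against 26.4 to 54.8% (median 40.8%) of Ascl1 block peaks with a Myod1 block. The number of blocks equals the number of pairs of IPs, and blocks that had an IP in common would not be independent. With only peaks found in every block of their list, the share of Ascl1 peaks in the Myod1 list was 29.35%. Myod1 lay closer to genes than Ascl1: 21.7% of its peaks (interval 21.2 to 22.3) had a midpoint within 1 kb of a gene end, against 14.8% (14.2 to 15.4) for Ascl1, where shifted peaks gave 3.25 and 3.26% (permutation, two-sided, p = 0.002, the smallest possible). Within 1 kb of a gene end lay 10.7% of Ascl1-only sites (interval 9.96 to 11.6), 18.02% of shared sites (17.1 to 18.9) and 23.6% of Myod1-only sites (22.9 to 24.3).

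Ascl1 activates proneural and Notch pathway genes during neurogenesis, and Myod1 activates the regulators and contractile genes of muscle. Gene lists were used to ask whether each factor in MEFs lay near the genes of its own lineage. Ascl1 peaks lay within 5 kb of a gene end at 15 of 42 proneural and Notch genes (35.7%), against 18.1% of other genes (odds ratio 2.51, interval 1.24 to 4.90, exact test, adjusted p = 0.0284). Myod1 peaks lay at 28 of 43 myogenic regulators (exact test, 65.1%, odds ratio 3.74, 1.93 to 7.53, adjusted p = 0.000267) and at 41 of 73 contractile genes (56.2%, odds ratio 2.57, 1.58 to 4.21, adjusted p = 0.000571), against 33.3% of other genes in both cases. Ascl1 peaks also lay at 15 of 43 myogenic regulators (exact test, 34.9%, odds ratio 2.42, 1.20 to 4.70, adjusted p = 0.0284). This call held under 6 of 11 alternatives (adjusted p 0.00139 to 0.655, exact tests). It ended with windows of 1 kb (odds ratio 1.32) and 50 kb (2.20), in the higher-scoring 50% of peaks (2.23), with peaks of every block (1.97) and against genes with a factor peak within 50 kb (1.87). Myod1 peaks lay at 14 of 42 proneural and Notch genes (33.3%), an odds ratio of 0.998 (0.485 to 1.96), which rose to at most 2.099 and did not pass under any alternative. Of the 20 tests of the 10 gene lists with these 2 peak lists (Fisher's exact tests, two-sided, Benjamini-Hochberg over the 20), 6 passed an adjusted threshold of 0.05, 5 of them higher and 1 lower than other genes, and 9 passed unadjusted.

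Among the proneural and Notch genes, 10 had peaks of both factors, 5 had an Ascl1 peak alone and 4 a Myod1 peak alone. The 5 included the Ascl1 gene itself, a transgene locus, which also counts among the 15 genes with an Ascl1 peak. The call of Ascl1 at this list still passed with the transgene loci left out. The Notch ligand genes Dll1 and Dll3 were in the Ascl1 list alone, with a peak at the edge of Dll1 (chromosome 17, 15376917 to 15377189, score 24.9, in 1 of 3 blocks) and a peak 563 bp from Dll3 (chromosome 7, 28302211 to 28302484, score 30.3, in 3 of 3 blocks). The Notch ligand gene Dll4, the homeobox gene Prox1 and the HMG-box gene Sox11 had 1 Myod1 peak each, in 1 of 6 blocks, and no Ascl1 peak. Zbtb18, which encodes a zinc finger repressor, had 3 Ascl1 and 4 Myod1 peaks. Gadd45g, which encodes a growth arrest protein, had 2 and 4, and the bHLH gene Atoh8 had 3 and 2. At Hes6, a bHLH gene induced by proneural factors, both lists had 2 peaks, and the nearest ones, at 91414090 to 91414615 (Ascl1, score 85.4) and 91414035 to 91414692 (Myod1, score 87.9) on chromosome 1, were found in every block. Set against the same split over all other genes, the odds of Ascl1 alone against Myod1 alone were 6.00 (interval 1.29 to 30.3) (Fisher's exact test, two-sided, p = 0.0105, adjusted p = 0.105 over the 10 lists). No list passed in that test of the difference, and 1 passed unadjusted. The difference passed with a window of 50 kb (odds ratio 9.53, adjusted p = 0.00793), with a window of 1 kb (6 and 0 genes, adjusted p = 9.6e-05) and with the Myod1 list cut by score to the length of the Ascl1 list (odds ratio 11.0, adjusted p = 0.0359, exact tests). Under the other settings it did not pass, with odds ratios down to 3.615 and adjusted p up to 0.788 (exact tests).

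Among the myogenic regulators, 14 had peaks of both factors, 14 had a Myod1 peak alone and 1, Ankrd1, which encodes an ankyrin repeat protein of striated muscle, had an Ascl1 peak alone (odds ratio 0.341, interval 0.00805 to 2.24, adjusted p = 0.615, Fisher's exact test). Those with a Myod1 peak alone included the Myod1 gene itself, a transgene locus. The call of Myod1 at this list passed under all 11 alternatives, among them the transgene loci left out. Mymk, which encodes the fusion protein myomaker (chromosome 2, 27061636 to 27072161), had 4 Myod1 and 2 Ascl1 peaks, and its Myod1 peak at 27071846 to 27072448 (score 32.4) was found in all 6 blocks. Chrng, an acetylcholine receptor subunit gene, had 3 Myod1 and 2 Ascl1 peaks, and Dok7, which encodes an adapter of the neuromuscular junction, had 4 and 1. Among the contractile genes, 17 had peaks of both factors, 24 a Myod1 peak alone and 1 an Ascl1 peak alone (odds ratio 0.198, interval 0.00481 to 1.22, adjusted p = 0.268, Fisher's exact test). Cacna1s, a calcium channel gene of skeletal muscle, had 2 Myod1 and 3 Ascl1 peaks, and Myh3, the embryonic myosin heavy chain gene, had 3 and 2. Mylk2, which encodes a myosin light chain kinase, had 4 Myod1 peaks and no Ascl1 peak. Atp2a1, which encodes the calcium pump of the sarcoplasmic reticulum, and Eno3, which encodes muscle enolase, had 3 Myod1 peaks each and no Ascl1 peak.

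Myod1 peaks also lay at 23 of 32 housekeeping genes (exact test, 71.9%, odds ratio 5.11, interval 2.28 to 12.6, adjusted p = 0.000236), with 4 peaks each at the glycolytic genes Gapdh and Aldoa and 2 at the translation factor gene Eef1a1. They lay at 4 of 40 liver genes (exact test, 10.0%, odds ratio 0.221, 0.0572 to 0.618, adjusted p = 0.00562), among them the apolipoprotein gene Apoa1 with 1 peak. Genes of the neuronal structural and synaptic list had an Ascl1 peak in 10 of 70 cases (odds ratio 0.752, 0.343 to 1.48, adjusted p = 0.667) and a Myod1 peak in 16 (odds ratio 0.591, 0.315 to 1.05, adjusted p = 0.149, exact tests). With the whole gene span extended by 5 kb as the window, the ratio for Ascl1 turned to 1.79 and passed (exact test, adjusted p = 0.037), as it did with the nearest gene (1.79, adjusted p = 0.0355). The neurofilament gene Nefh and the internexin gene Ina each had 1 Ascl1 peak and no Myod1 peak once control peaks were removed, and with control peaks kept they lay in 4 and 3 of the factor lists. With only peaks found in every block, the calls of Myod1 at contractile genes (odds ratio 0.924, adjusted p = 1), housekeeping genes (1.30, adjusted p = 0.679) and liver genes (0.322, adjusted p = 0.561) ended, as did that of Ascl1 at myogenic regulators (1.97, adjusted p = 0.425, exact tests). The call of Myod1 at myogenic regulators stayed (6.11, exact test, adjusted p = 2.7e-05). Among genes with any factor peak within 50 kb, the calls of Ascl1 at proneural and Notch genes (1.96, adjusted p = 0.141) and at myogenic regulators (1.87, adjusted p = 0.141) and of Myod1 at contractile genes (1.88, adjusted p = 0.0643) ended in the exact tests. With a window of 50 kb that of Myod1 at liver genes ended (0.655, exact test, adjusted p = 0.267).

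**Figure D2:**
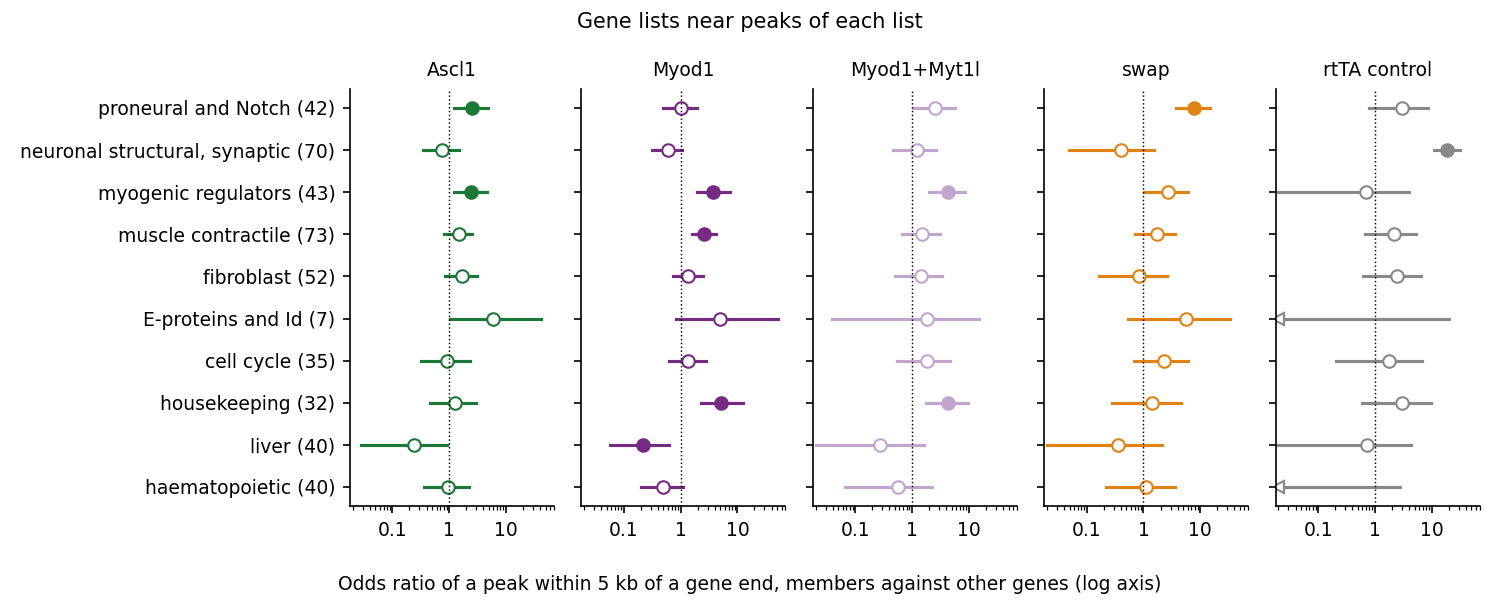
Odds ratio of a peak within 5 kb of a gene end for the members of each gene list against all other protein-coding genes (log axis), 1 panel per peak list, with the number of genes beside each list name; lines are 95% intervals, drawn only as far as the axis reaches, filled points passed an adjusted threshold of 0.05, and arrowheads mark a ratio of 0. Ascl1 and swap peaks passed at proneural and Notch genes (2.51 and 7.71), Ascl1, Myod1 and Myod1+Myt1l peaks at myogenic regulators (2.42, 3.74 and 4.21), Myod1 and Myod1+Myt1l peaks at housekeeping genes (5.11 and 4.25), Myod1 peaks at contractile genes (2.57) and, below 1, at liver genes (0.221), and control peaks at neuronal genes (18.7).

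Myt1l represses non-neuronal genes in neurons, and the Myod1+Myt1l list was used to ask which sites Myod1 held when Myt1l was added. Myod1+Myt1l peaks lay mostly at sites of Myod1. Of the Myod1+Myt1l peaks, 89.8% (3032 of 3377, interval 88.7 to 90.8) overlapped a Myod1 peak and 61.7% (2085 peaks, 60.1 to 63.4) an Ascl1 peak, where shifted peaks gave 0.783 and 0.438% (permutation tests, one-sided, p = 0.001, the smallest possible). In the other direction, 16.5% of Ascl1 peaks (2097 of 12683, 15.9 to 17.2) and 14.7% of Myod1 peaks (3013 of 20484, 14.2 to 15.2) overlapped a Myod1+Myt1l peak, so the order of the factors turned. By membership, 58.1% of the Myod1+Myt1l peaks were in both lists, 31.7% in the Myod1 list alone, 3.67% in the Ascl1 list alone and 6.54% in neither. The Myod1+Myt1l peaks shared with Myod1 had a median score percentile of 51.9 against 43.1 for the others, a difference that did not pass (permutation test, two-sided, p = 0.110). The Myod1 list came from more IPs and was longer. With only Ascl1 and Myod1 peaks found in every block of their own list, the shares were 40.9% with Myod1 and 32.1% with Ascl1.

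The swap construct, a Myod1 with the basic and C-terminal parts of Ascl1, was compared with both parent factors to ask whose sites it occupied. The basic region of a bHLH protein contacts DNA, and the helix-loop-helix part of the swap construct was that of Myod1. Of its peaks, 71.7% (2238 of 3121, interval 70.1 to 73.3) overlapped a Myod1 peak and 69.0% (2152 peaks, 67.3 to 70.6) an Ascl1 peak, where shifted peaks gave 0.823 and 0.457% (permutation tests, one-sided, p = 0.001, the smallest possible). In the other direction, 17.0% of Ascl1 peaks (2151 of 12683, 16.3 to 17.6) and 10.9% of Myod1 peaks (2223 of 20484, 10.4 to 11.3) overlapped a swap peak, so the order of the factors turned here too. By membership, 57.0% of swap peaks were in both lists, 11.98% (interval 10.9 to 13.2) in the Ascl1 list alone, 14.7% (13.54 to 16.03) in the Myod1 list alone and 16.3% (15.1 to 17.6) in neither. The swap peaks shared with Ascl1 had a median score percentile of 56.1 against 38.3 for the others, and those shared with Myod1 55.3 against 40.0 (permutation tests, two-sided, p = 1e-05 each, the smallest possible). Of the swap peaks, 28.4% (interval 26.8 to 30.0) overlapped a Myod1+Myt1l peak, and 26.1% of Myod1+Myt1l peaks (24.6 to 27.6) a swap peak. With only Ascl1 and Myod1 peaks found in every block, the shares were 38.6% with Ascl1 and 28.8% with Myod1.

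Site by site, the swap construct held 6.57% of 5601 Ascl1-only sites (interval 5.95 to 7.25), 25.5% of 6982 shared sites (24.5 to 26.5) and 3.27% of 13471 Myod1-only sites (2.99 to 3.59). The odds ratio of Ascl1-only against Myod1-only sites was 2.08 (1.80 to 2.40, Fisher's exact test, two-sided, p = 4.6e-23). Myod1+Myt1l held 2.27% of Ascl1-only sites (1.91 to 2.69), 28.2% of shared sites (27.2 to 29.3) and 7.74% of Myod1-only sites (7.30 to 8.20), an odds ratio of 0.277 (0.228 to 0.334, Fisher's exact test, two-sided, p = 6.8e-55). Among sites held by exactly 1 of these 2 constructs, the swap construct held 341 Ascl1-only and 348 Myod1-only sites, and Myod1+Myt1l held 100 and 949. The odds ratio between them was 9.30 (7.16 to 12.1, Fisher's exact test, two-sided, p = 1.5e-78). These constructs differ in Myt1l as well as in the Ascl1 parts, so the ratio does not isolate the swapped parts. With midpoints within 100 bp as the rule for a shared site the ratio was 4.34, with only peaks of every block 5.39, and over the 18 pairs of single Ascl1 and Myod1 blocks 4.12 to 7.70. With the midpoint rule the ratio of Myod1+Myt1l was 0.8245.

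**Figure D3:**
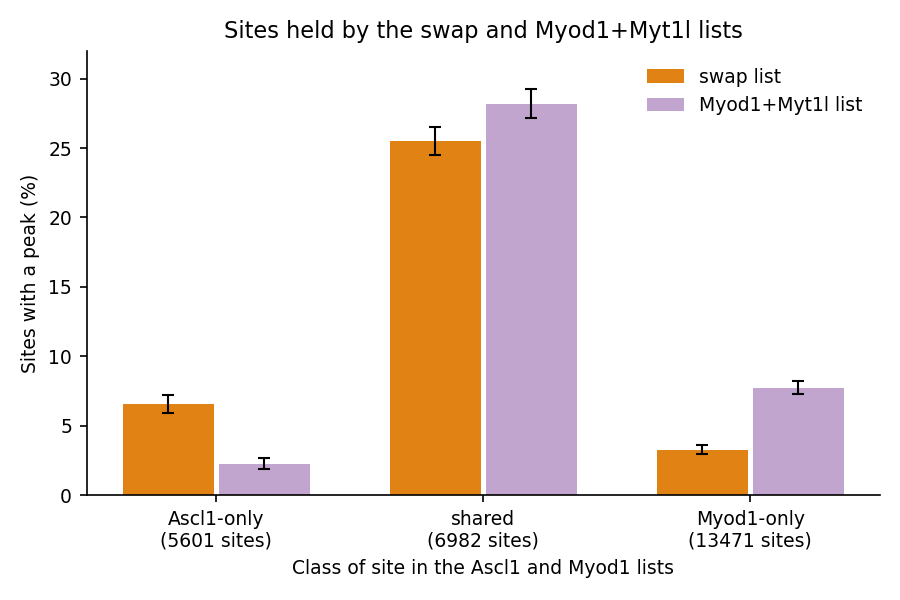
Percent of sites with a swap or Myod1+Myt1l peak (vertical axis) among Ascl1-only, shared and Myod1-only sites (horizontal axis, with the number of sites); bars are the shares and lines the 95% Wilson intervals. The swap construct held 6.57% of Ascl1-only and 3.27% of Myod1-only sites, and Myod1+Myt1l held 2.27% and 7.74%.

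The same gene lists were used to ask whether the Ascl1 parts of the swap construct went with peaks at neuronal or at muscle genes. Swap peaks lay near proneural and Notch genes more often than near other genes: 15 of 42 (35.7%) had one within 5 kb, against 6.72% of other genes (odds ratio 7.71, interval 3.80 to 15.1, exact test, adjusted p = 9.4e-07). For Myod1+Myt1l, peaks lay at 12 of 43 myogenic regulators (27.9% against 8.42%, odds ratio 4.21, 1.97 to 8.45, adjusted p = 0.00165) and at 9 of 32 housekeeping genes (28.1%, odds ratio 4.25, 1.73 to 9.56, adjusted p = 0.00674, exact tests). These were the 3 of 20 tests that passed (Fisher's exact tests, two-sided, Benjamini-Hochberg over the 20; 5 passed unadjusted). Proneural and Notch genes had a Myod1+Myt1l peak in 8 of 42 cases (odds ratio 2.55, 1.02 to 5.63, adjusted p = 0.0976, past the threshold under 3 of 8 alternatives), and myogenic regulators had a swap peak in 7 of 43 (odds ratio 2.68, 1.01 to 6.12, adjusted p = 0.0976, exact tests). The transgene loci count here: Ascl1 is among the 15 genes with a swap peak, and Myod1 among the 12 and the 7 myogenic regulators.

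Of the proneural and Notch genes, 7 had peaks of both constructs, 8 a swap peak alone and 1, Rgs16, a regulator of G protein signalling, a Myod1+Myt1l peak alone. The 8 included the Ascl1 gene, a transgene locus. Hes6 had 2 peaks in each list, and the swap peak nearest to it (chromosome 1, 91414111 to 91414623, score 29.1) ranked 9 in the swap list after control peaks were removed. The homeobox gene Dlx3 and Hes1, a Notch effector gene, had 2 swap peaks and 1 Myod1+Myt1l peak each. Atoh8 had 2 swap peaks and the corepressor gene Cbfa2t3 had 2, where Myod1+Myt1l had none. The Ascl1 peaks of Dll1 and Dll3 had no counterpart in the swap list. The odds of a swap peak alone against a Myod1+Myt1l peak alone, set against all other genes, were 11.3 (interval 1.51 to 502, Fisher's exact test, two-sided, p = 0.00503), with an adjusted p of 0.0503 over the 10 lists, so the difference did not pass. With the gene nearest to each peak in place of the window it passed (odds ratio 5.81, adjusted p = 0.0277, exact test), the 1 of 8 alternatives under which it did. With a window of 1 kb, 3 genes had a swap peak alone and 2 a Myod1+Myt1l peak alone (odds ratio 1.94, adjusted p = 1), and with 50 kb the ratio was 4.28 (adjusted p = 0.109, exact tests). Without the genes of the transgene loci it was 9.90 (adjusted p = 0.108, exact test).

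At muscle genes, Mymk had 2 Myod1+Myt1l peaks and no swap peak, Dok7 had 1 and 0, and Chrng had 0 and 1. The differences between the constructs did not pass for myogenic regulators (3 genes with swap alone, 8 with Myod1+Myt1l alone, odds ratio 0.524, interval 0.0894 to 2.19, adjusted p = 0.832) or contractile genes (5 and 6, odds ratio 1.17, 0.281 to 4.62, adjusted p = 0.856; Fisher's exact tests, two-sided). Neuronal structural and synaptic genes had a swap peak in 2 of 70 cases (odds ratio 0.404, 0.0479 to 1.52, adjusted p = 0.424) and a Myod1+Myt1l peak in 7 (odds ratio 1.20, 0.464 to 2.63, adjusted p = 0.738, exact tests). With control peaks kept, both passed, with odds ratios of 3.67 (adjusted p = 0.000493) and 2.55 (adjusted p = 0.0156) in the exact tests. The call of Myod1+Myt1l at myogenic regulators ended with a window of 1 kb (odds ratio 3.34, exact test, adjusted p = 0.0762). The call at housekeeping genes ended under 5 of 7 alternatives, with adjusted p of 0.00243 to 0.437 over all 7. The odds ratio was then 3.81 at 1 kb, 2.99 against genes with a factor peak within 50 kb, 2.82 with the extended gene span, 1.80 at 50 kb and 1.74 with the nearest gene.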

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

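The test of open promoters at control peaks, the use of peaks found in every block or in single blocks, and the use of the strongest peaks in the number of the swap list were chosen only after results were seen. Gene lists and the comparisons of factor lists were fixed before the data were examined. Exceptions were the windows at gene ends in place of start sites and the per-list difference between the swap construct and Myod1+Myt1l. The gene list tests of the control were not planned. Myod1 peaks at housekeeping genes were first listed for weighing and were set aside for the control peaks at neuronal genes. That odds ratio was 5.11 and ranged from 1.301 with peaks found in every block to 16.7 with a window of 50 kb. It passed under 9 of 10 alternatives (adjusted p 9.64e-06 to 0.679), and no explanation for it was tested.

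The swap construct and Myod1+Myt1l differed in whose sites they held: in a test of the difference itself, the odds ratio of Ascl1-only against Myod1-only sites was 9.30 (interval 7.16 to 12.1). Weak peaks near the calling threshold were predicted to bring it to 1 at sites found in every block of their own list, where it was 25.0 (15.0 to 41.8), and with whole lists reduced to such peaks, a reading seen first, it was 5.39. A single deviating block would have ended it in some pair of blocks, but the lowest lower bound over 18 pairs was 3.33. FLAG background stays open: the ratio was taken without control peaks and was 7.60 (5.89 to 9.84) with them kept, and tests by nearness to control peaks or by their removal were run and dropped, since the class of site and the earlier removal set their outcome. So the ratio was not confined to a single block of the Ascl1 and Myod1 lists. The swap and Myod1+Myt1l lists have 1 block each and stayed whole, so these tests do not address weak peaks or a deviating IP there. Myod1+Myt1l was also an IP of Myod1, so sites of every Myod1 block can favour it and keep the ratio above 1 whatever the cause. The test at such sites therefore cannot decide on weak peaks, and the rise to 25.0 adds no support. Depth, batch and amount of protein were not tested, and the Ascl1 parts and the absence of Myt1l stay open together as biological explanations.

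The swap list shared more of its peaks with the control than the Ascl1 and Myod1 lists did, 8.72% (interval 7.82 to 9.71) against 0.697 and 2.20%. If a shorter list simply kept the strongest peaks, the strongest 3419 Ascl1 or Myod1 peaks would share as much, but the higher of these shares was 2.28% for Myod1 (upper bound 2.84) and the other 0.585% for Ascl1. If merging over blocks lowered the share, single blocks would reach it, but the highest of 9 was 3.92% (upper bound 4.44). Both tests concern the share of a list's own peaks. In the other direction the Myod1 list met more of the 1125 control peaks than the swap list, 42.04% against 26.7%. The Ascl1 list met 8.44%. So the swap list did not hold more of the control peaks than the whole Myod1 list, which was merged over 6 blocks into 20944 peaks. Single Myod1 blocks, of 6040 to 16357 peaks, had 185 to 304 peaks that overlapped a control peak, against 298 of 3419 for swap. The order in this direction may thus rest on the length of the merged list. Depth and the efficiency of the IPs were not tested and stay open, and no biological explanation was tested.

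The control list, which the comparisons between factors use only to remove peaks, held a signal of its own: the odds ratio of a control peak near genes of the neuronal list was 18.7 (interval 11.0 to 31.2). For gene length, 10000 random lists matched on length held at most 10 genes with a control peak (median 2) against 27 observed. The fixed windows of 5 kb at gene ends left length little room to enter the count, so this test adds little. Open promoters of active genes are argued against by the housekeeping genes, of which 9.38% (3.24 to 24.2) had a control peak against 38.6% (28.0 to 50.3) of neuronal genes. A candidate explanation is that the FLAG beads pulled down chromatin at RE1 sites, which the repressor REST binds at neuronal genes in non-neuronal cells: 18 of 21 REST targets in the list had a control peak against 9 of 49 other members (odds ratio 26.7, interval 5.68 to 160, Fisher's exact test, two-sided, p = 1.6e-07). Of 34 REST targets outside the list 19 had one, against 3.16% of 21684 other genes (odds ratio 38.8, 18.6 to 82.3, Fisher's exact test, two-sided, p = 4.8e-20). The targets were written down from general knowledge before the test, RE1 motifs were not analysed here, and the pattern was found and tested in the same data, so this remains a hypothesis.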

How the results depend on the processing

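Peaks found in every block, single blocks, the gene span extended by 5 kb, the transgene loci left out, the Myod1 list reduced by score for gene lists, the strongest peaks in the number of the swap list and the per-list difference between the swap construct and Myod1+Myt1l were chosen only after the results were seen. No paired analysis was possible because 1 list per group was used and values per replicate were not analysed here, so leaving out each replicate was not run. E-box results, with their GC-matched and window alternatives, were not run, since genome sequence was not used here. Depth limits are unknown from these lists.

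The odds ratio of Ascl1-only sites ranged over 10 alternatives from 1.51 to 2.96 for the swap construct, from 0.255 to 0.8245 for Myod1+Myt1l and from 4.12 to 9.61 between them, with the same direction and past the threshold throughout. Shares ranged from 26.4 to 56.1% (Ascl1 with Myod1), 17.1 to 52.5% (Myod1 with Ascl1), 40.9 to 90.1% and 32.1 to 61.7% (Myod1+Myt1l with Myod1 and Ascl1), and 28.8 to 71.8% and 38.6 to 69.0% (swap with Myod1 and Ascl1), each above shifted peaks. A random draw from the other lists' sites gave higher shares than observed for Ascl1 with Myod1 (94.5%) and Myod1 with Ascl1 (85.5%). That follows from its construction, since the partner list makes up most of the sites drawn from. The draw was also higher for swap with Myod1 (77.85% against 71.7% observed). Every drawn site lies in another list, but 16.3% of swap peaks lay in neither the Ascl1 nor Myod1 list. So this draw was no test of swap peaks.

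Of 20 tests with Ascl1 or Myod1 peaks, 6 passed. That count was 13 with the nearest gene, 13 with the extended gene span, 3 with the background of genes near a factor peak and 2 with peaks found in every block. Of 20 with swap or Myod1+Myt1l peaks, 3 passed, against 5 at 50 kb, 6 with the nearest gene and 6 with control peaks kept. At 1 kb fewer passed. There the Myod1+Myt1l calls at myogenic regulators and at housekeeping genes ended (adjusted p = 0.0762 each), and that at proneural genes newly passed (adjusted p = 0.00612, exact tests). Differences between Ascl1 and Myod1 passed for 0 lists, against 1 at 1 kb, 1 at 50 kb and 2 with Myod1 reduced by score. Those between the swap construct and Myod1+Myt1l passed for 0, against 1 with the nearest gene. The cause was not tested. At 1 kb the proneural difference and at 50 kb Myod1 at E proteins had a count of 0 and no finite ratio.

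Other results that kept no direction are odds ratios of gene lists, most past the threshold in neither setting (45 of 50), and the cause was not tested. At 1 kb they were cell cycle with Ascl1 1.67, neuronal and contractile with Myod1+Myt1l 0.918 and 0.879, and haematopoietic with swap 0.637. At 50 kb they were proneural, Myod1 1.20, neuronal, cell cycle and haematopoietic, Ascl1 1.35, 1.61 and 1.29, haematopoietic, Myod1 1.61 and Myod1+Myt1l 1.13, and fibroblast, swap 1.45. With the nearest gene they were proneural, Myod1 1.47, neuronal, cell cycle and housekeeping, Ascl1 1.79, 1.01 and 0.840, and with swap neuronal 1.22, fibroblast 3.50, cell cycle 0.886, housekeeping 0.630 and haematopoietic 0.766. With control peaks kept they were proneural and neuronal, Myod1 1.30 and 1.13, neuronal and haematopoietic, swap 3.67 and 0.997, and the neuronal differences 0.314 (Ascl1 against Myod1) and 1.70 (swap against Myod1+Myt1l). With Myod1 reduced by score the neuronal Ascl1 against Myod1 difference was 0.670, and at random proneural, Myod1 was 1.04. With the background of genes near a factor peak, cell cycle, Myod1 was 0.9055 and housekeeping, Ascl1 0.8355. In the top-scoring peaks they were proneural, Myod1 1.21, neuronal and haematopoietic, Ascl1 1.08 and 1.08, neuronal, Myod1+Myt1l 0.989, cell cycle, housekeeping and haematopoietic, swap 0.994, 0 and 0.867, and the neuronal swap against Myod1+Myt1l difference 1.13. With peaks of every block they were proneural and contractile, Myod1 2.099 and 0.924, and contractile and haematopoietic, Ascl1 0.641 and 1.215. With the extended gene span they were proneural and neuronal, Myod1 1.27 and 1.17, neuronal and housekeeping, Ascl1 1.79 and 0.893, and neuronal, fibroblast and haematopoietic, swap 1.20, 2.51 and 0.755. Without transgene loci proneural, Myod1 was 1.075.

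Of the other list results and named genes, 515 kept their side, 28 newly passed, 16 no longer passed and 103 moved. Of 36 named genes, the number of lists with a peak nearby moved for 21 at 1 kb, 20 at 50 kb, 14 with the nearest gene, 17 in the top-scoring peaks, 22 with peaks of every block, 5 with Myod1 reduced by score, 2 with control peaks kept and 2 with the extended span. Adjusted p over alternatives ran from 0.00056 to 0.141 for Ascl1 at proneural genes, 0.00139 to 0.655 for Ascl1 and 6.25e-06 to 0.034 for Myod1 at myogenic regulators, 0.000112 to 1 for Myod1 at contractile genes, 4.87e-09 to 0.000526 for swap at proneural genes and 2.41e-05 to 0.0762 for Myod1+Myt1l at myogenic regulators.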

Other observations

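The shares of peaks on chromosome X were computed after the data were seen. The gene list tests of the factor lists in this part were planned, and those of the control were not. The factors also lay near genes outside the neuronal and muscle lists. At Snai1, which encodes a repressor of epithelial genes in mesenchymal cells, there were 2 Ascl1, 5 Myod1 and 2 swap peaks. At Ccnd1, the cyclin D1 gene, there were 2 Myod1 and 3 swap peaks and no Ascl1 peak. Id1 and Id3 encode inhibitors that bind E proteins, the partners of bHLH factors. Id1 had 4 Ascl1, 3 Myod1, 1 Myod1+Myt1l and 3 swap peaks, and Id3 had 2 Ascl1 and 4 Myod1 peaks. Among the genes with most peaks were Cirbp, which encodes a cold-inducible RNA-binding protein (5, 7, 3 and 4 peaks of Ascl1, Myod1, Myod1+Myt1l and swap), and Scx, a bHLH gene of tendon (4, 5, 3 and 4).

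The remaining list results did not pass at 5 kb (Fisher's exact tests, two-sided). For Ascl1 the odds ratios were 1.48 for contractile (18 of 73), 1.67 for fibroblast (14 of 52), 6.03 for E protein and Id (4 of 7), 0.934 for cell cycle (6 of 35), 1.26 for housekeeping (7 of 32), 0.237 for liver (2 of 40) and 0.958 for haematopoietic genes (7 of 40). For Myod1 they were 1.35 for fibroblast (21 of 52), 4.99 for E protein and Id (5 of 7), 1.33 for cell cycle (14 of 35) and 0.498 for haematopoietic genes (8 of 40). For swap peaks they were 1.70 for contractile (8 of 73), 0.842 for fibroblast (3 of 52), 5.51 for E protein and Id (2 of 7), 2.30 for cell cycle (5 of 35), 1.42 for housekeeping (3 of 32), 0.352 for liver (1 of 40) and 1.12 for haematopoietic genes (3 of 40). For Myod1+Myt1l they were 1.53 for contractile (9 of 73), 1.41 for fibroblast (6 of 52), 1.81 for E protein and Id (1 of 7), 1.81 for cell cycle (5 of 35), 0.277 for liver (1 of 40) and 0.569 for haematopoietic genes (2 of 40). Fibroblast genes passed with the nearest gene for all 4 factor lists, with odds ratios of 3.45 (Ascl1), 3.63 (Myod1), 2.52 (Myod1+Myt1l) and 3.50 (swap), and adjusted p over all alternatives of 0.000105 to 0.505, 0.000105 to 0.88, 0.0253 to 0.974 and 0.00138 to 1.

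For the control, odds ratios were 3.04 for proneural (4 of 42), 0.684 for myogenic (1 of 43), 2.12 for contractile (5 of 73), 2.40 for fibroblast (4 of 52), 1.75 for cell cycle (2 of 35), 2.98 for housekeeping (3 of 32) and 0.737 for liver genes (1 of 40), with 0 of 7 E protein and Id genes and 0 of 40 haematopoietic genes. Within 1 kb of a gene end lay 34.0% of control peaks (interval 31.3 to 36.9), 26.9% of Myod1+Myt1l peaks (25.4 to 28.4) and 25.0% of swap peaks (23.5 to 26.6).

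Chromosome X held 0.744% of Ascl1, 0.731% of Myod1, 0.422% of Myod1+Myt1l, 0.468% of swap and 0.444% of control peaks, against 4.42% of the genes used. The share was low in each of the 5 lists, and no test of it was run.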
